A study of Mus musculus with 6 samples.

How the data were processed

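Total RNA of Tot2 cells was labelled with Cy3 and hybridised to 6 Agilent mouse arrays of 62976 spots, 2 for each of the 3 groups. Per the file headers, the values are intensity: spot brightness read by Agilent Feature Extraction 10.7.3.1, background-subtracted and detrended within each array, with no normalization between arrays. The deposited value table also holds intensity; each of its columns was the processed signal of that array times 1 factor (0.642 to 1.388), to within 1% for all but 93 to 95 probes per array, and was used as an alternative. The lowest signal well above background lay at log2 -5.42 to -4.32 relative to the 75th percentile.

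Control spots were left out, which kept 59305 spots of 55681 probes, and replicate spots of a probe were averaged and 75 probes were dropped because the software had marked their spots. Log2 of the processed signal minus the 75th percentile of each array was the measure. Of the probes, 28390 carried an accession of the RefSeq form and 26762 of these were matched to a gene in the annotation (GRCm38.p6), 1628 were not, and 28919 probes had no gene name, among them 16194 named by a genome region on mm9. The array files give no gene symbols, no probe sequences were used here, and no coordinates are given for named genes. The matched probes stood for 20284 genes, 20263 with values on all 6 arrays. For the 5396 genes with several probes, the probe with the highest mean log2 signal over the 6 arrays was used, a choice made without the groups; of 3460 genes with several tested probes, 30, 3 and 21 had probes called in both directions in the comparisons of IRF8-labelled cells with control, KLF4-labelled cells with control, and IRF8-labelled with KLF4-labelled cells. Genes were tested if the probe was well above background on both arrays of at least 1 group, which left 13247. Probes for near-identical gene families (stefins, MHC genes, alpha globins, Bcl2a1) may read more than 1 member. Ly6c2, which was to be named whatever its value, was not matched on the array.

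All 6 arrays entered a single limma fit with 3 groups (3 residual degrees of freedom, empirical Bayes spread), 2-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The comparisons, tests, gene lists, rule for named genes and most alternatives were chosen before the data were examined. Fold changes against a group with no array above background are given as at least the ratio to the lowest signal well above background, and none is given where both groups were below it. Medians of gene lists are also given with such genes at their bound. Genes named are, per comparison, the 10 largest rises and 10 largest falls among genes past the threshold whose arrays do not overlap between groups, clone and locus names left out, up to 4 members of each list with the largest changes past the threshold, and Irf8, Klf4, Csf1r, Cd14, Adgre1, Mpo, Gapdh and Actb; a few that this rule or a list would name are not reported here, whatever their values, and stay in every count. List members that moved against their list and genes given as shared examples were named after their values were seen. Simulated data with 13247 genes of which 200 changed, in 10 draws, tested the procedure. A log2 change of 1 was recovered in 71.4% and 71.7% of genes for IRF8 and KLF4 against control. A change of 2 was recovered in 94.9% and 95.5%, and 3.93% and 5.10% of calls were false. The data had 61.5% and 19.2% of genes called, so these rates need not carry over.

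The 18 lists fixed in advance are each named with their results. Lists were tested with camera at a preset correlation of 0.01 over all genes tested, adjusted over the 18 lists of a comparison, and again with an estimated correlation and with fry, which tests whether a list's genes move on balance in a direction without reference to other genes. Where the estimate lay below 0.01, a call lost with that setting does not show correlation between genes. Another 8 lists were written after the largest changes had been seen and before their own values were.

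The replicate number follows both the experiment and the slide. Deviations of arrays from their group means correlated across genes at r = 0.282 (control with IRF8), 0.321 (control with KLF4) and 0.391 (IRF8 with KLF4), so the numbers pair the samples, and a fit with the replicate number as a block was run for every result. Its value is given beside a result where it changed a call or moved a count over 1.5 times, for a list by at least 2 genes. Values of a list with another scaling or normexp are given where a count moved that far, or the median by over 1.5 times and at least 0.1 or in sign. Other alternatives were quantile normalization, median scaling, normexp background correction with an offset of 50, the deposited value table, no filter on dim probes, genes above background on all 6 arrays, a floor on dim signals, the mean of a gene's probes, every probe by itself, limma with trend and robust settings, only the 2 groups compared, an adjusted p threshold of 0.01, at least 2-fold, and leaving out each array in turn, where the lone array of a group is assumed to vary like the others. Normexp was run on median signals because the files hold no mean signal. Scaling on spike-in control spots, the block with median scaling or quantile normalization, median scaling of lists and single genes, normexp for lists, and counts at 2-fold or more with the block or without an array were added after the data had been seen. Groups of 2 allow neither a test for outlying arrays nor a count of other splits. The covariance of the comparisons with control was set beside 100 simulated draws with shared control arrays. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.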

Results

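RNA was profiled in Tot2 cells, a line of myeloid progenitors that came from an Irf8-deficient mouse. The cells had received by retrovirus an empty control vector, a vector for IRF8 or a vector for KLF4, both of them transcription factors of the monocyte lineage. They were kept in 5 ng/ml granulocyte-macrophage colony-stimulating factor, put under 2 µg/ml puromycin from 48 hr after transduction and harvested on day 4. Each of the 3 groups was measured on 2 arrays with a single dye, numbered 1 and 2 for the 2 experiments that the design text calls independent. Between 47.7% and 57.5% of 55681 probes were well above background per array, no spot was saturated, and the 75th percentile of intensity ran from 436 to 974. Across the 13247 genes tested, log2 signals of the 2 arrays of a group correlated at r = 0.993 to 0.995 and those of different groups at r = 0.889 to 0.960; genes are not independent replicates. The small number of arrays limits the precision: an exact two-sided permutation test of 2 values against 2 cannot fall below p = 0.333, so genes were tested with limma, which pools the spread over all genes. Every SE given is on the log2 scale.

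Irf8, the gene knocked out in the mouse that gave the line, and Klf4 were read first. The single Irf8 probe (A_52_P354823) gave log2 signals of 0.49 and 0.64 on the control arrays, 2.94 and 3.05 on the IRF8-labelled arrays and 2.18 and 2.16 on the KLF4-labelled arrays, relative to each array's 75th percentile. Irf8 signal was 5.39-fold above control on IRF8-labelled arrays (log2 2.43 ± 0.10 (SE), n = 2 per group, limma adjusted p = 5.37e-05) and 3.04-fold above control on KLF4-labelled arrays (log2 1.60 ± 0.10 (SE), limma adjusted p = 6.06e-04). The difference between the transduced groups was 0.83 ± 0.10 (SE) with limma adjusted p = 0.00210, and 0.67 with adjusted p = 0.213 when arrays were scaled on their spike-in controls. The single Klf4 probe (A_55_P2122020) read -1.62 and -1.28 on control arrays and 4.46 and 4.61 on IRF8-labelled arrays, a rise of 63.2-fold (log2 5.98 ± 0.16 (SE), limma adjusted p = 1.87e-05). On the KLF4-labelled arrays it read -1.56 and -1.33, a difference from control of 0.00 ± 0.16 (SE) (95% interval -0.40 to 0.41, limma adjusted p = 0.987). Probe positions are not given in the sources used here, so neither probe is shown to detect the transduced sequence. Because Klf4 signal was not higher on the arrays labelled KLF4, groups are called IRF8-labelled and KLF4-labelled throughout, and every direction given for them rests on the labels.

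Csf1r, the receptor for macrophage colony-stimulating factor, rose 45.6-fold in IRF8-labelled and 13.8-fold in KLF4-labelled cells, and Adgre1, which encodes the macrophage antigen F4/80, rose 21.3-fold and 7.30-fold. The Csf1r values are those of A_55_P2025078, the brightest of 3 probes: A_52_P602091 gave 64.2-fold and 18.2-fold, and A_55_P2025073 6.90-fold and 2.84-fold. Cd14, a co-receptor for bacterial lipopolysaccharide, rose 4.00-fold and 3.12-fold (over these 3 genes and both comparisons, SE 0.09 to 0.24 and limma adjusted p = 7.42e-06 to 0.00177). Csf1r and Adgre1 were 3.30-fold and 2.92-fold higher in IRF8-labelled than in KLF4-labelled cells (SE ≤ 0.24, adjusted p ≤ 0.00505). For Cd14 that difference was 0.36 ± 0.11 (SE) with adjusted p = 0.0426. The call was lost without any 1 of the 6 arrays, and with median (adjusted p = 0.0736) or spike-in scaling (0.749). Mpo, the myeloperoxidase gene of granules, differed from control by -0.87 ± 0.36 (SE) in IRF8-labelled cells (adjusted p = 0.0898) and -0.25 ± 0.36 (SE) in KLF4-labelled cells (adjusted p = 0.637). The former passed with the block (adjusted p = 0.00369), quantile normalization (0.00205) or spike-in scaling (0.0306). The direct difference in Mpo was -0.62 ± 0.36 (SE) (adjusted p = 0.214; 0.0118 with the block and 0.00386 with quantile normalization). Of the reference genes, Gapdh differed by 0.04, -0.13 and 0.17 in the 3 comparisons (adjusted p = 0.912, 0.742 and 0.639). The first was -0.08 with spike-in scaling and the second 0.04 with quantile normalization. All 7 probes lay from -0.13 to 0.17, and the brightest is given. Actb differed by 0.36, 0.04 and 0.32 (adjusted p = 0.397, 0.935 and 0.476). The block brought Actb past the threshold in the comparisons of IRF8-labelled cells with control (adjusted p = 0.0135) and with KLF4-labelled cells (0.0225), and quantile normalization did so in the former (0.00559).

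**Figure D1:**
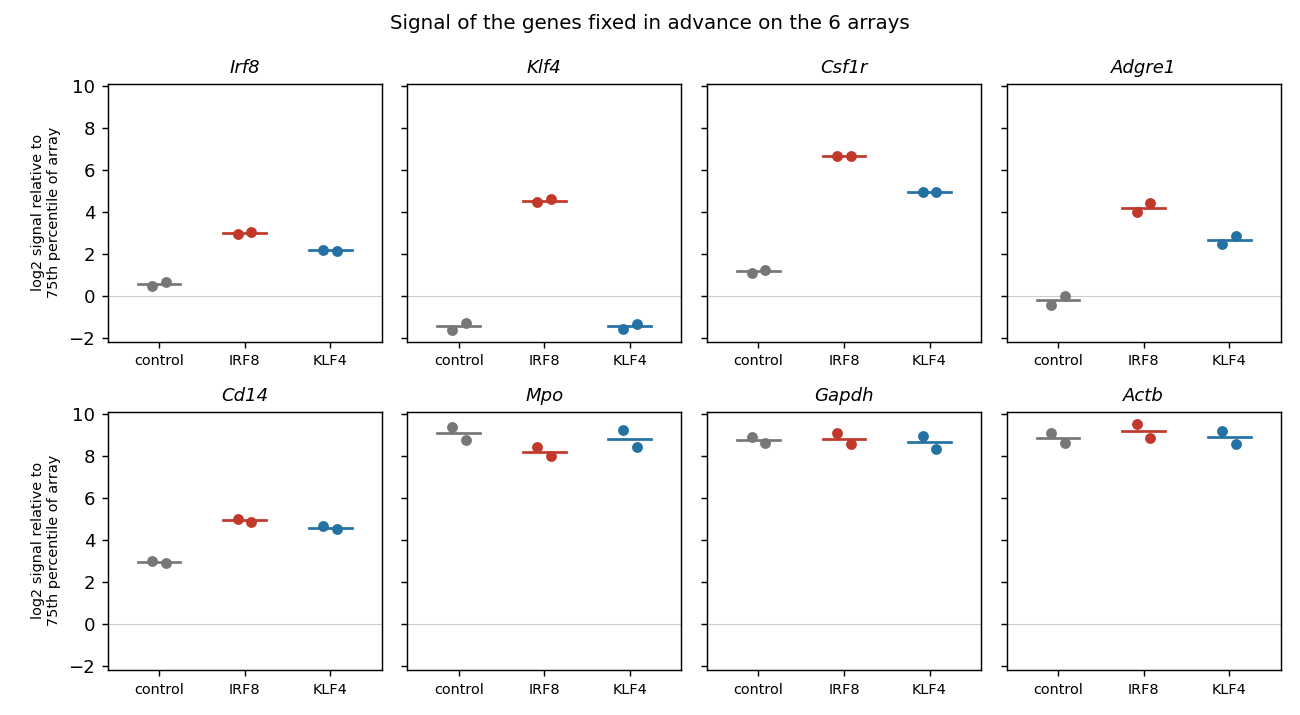
Log2 signal relative to the array's 75th percentile (vertical axis) for Irf8, Klf4, Csf1r, Adgre1, Cd14, Mpo, Gapdh and Actb on the 6 arrays, grouped as control, IRF8 and KLF4 by label; points are arrays and lines are group means. The Klf4 points of the KLF4-labelled arrays lie at the control level.

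The comparison of IRF8-labelled cells with control asked which genes differed in cells given IRF8, cells that the design text calls monocyte-like. IRF8-labelled cells gained transcripts of antigen presentation, lysosomes and monocyte chemokines and lost transcripts of neutrophil granules. These list calls were lost with an estimated correlation (adjusted p = 0.0510 to 0.255). Ctss, the lysosomal protease cathepsin S, rose at least 8051-fold, the MHC class II genes H2-Ab1 and H2-Eb1 rose at least 2445-fold and at least 1219.7-fold, and Lgmn, the lysosomal protease legumain, rose at least 1251-fold. SE reached 0.69 and adjusted p 1.31e-04. Ccl2, a chemokine that attracts monocytes, rose at least 1418-fold, Itgax, the integrin CD11c of dendritic cells and macrophages, at least 929-fold, Tgfbi, a matrix protein induced by transforming growth factor beta, at least 1750.3-fold, and the scaffold protein gene Ahnak at least 1949-fold. SE reached 0.23 and adjusted p 9.44e-06. Wfdc17, a small secreted protein of activated macrophages, rose 3864-fold, with 1 of the 2 control arrays above background (log2 11.92 ± 0.25 (SE), adjusted p = 1.12e-05). Granule genes were among the deepest falls: Ltf (lactoferrin) fell 82.5-fold, Ngp (neutrophilic granule protein) 73.9-fold, Camp (cathelicidin) 58.6-fold, the neutrophil surface gene Cd177 56.7-fold, the stefin gene Stfa2 53.5-fold and Fcnb (ficolin B) 33.9-fold. SE reached 0.37 and adjusted p 1.54e-04. Itgb2l and Ceacam10 fell 95.2-fold and 42.4-fold with 1 of the 2 IRF8-labelled arrays above background, and Ankrd22 and Gtsf1l fell at least 23.2-fold and at least 28.9-fold. SE reached 0.26 and adjusted p 5.66e-05.

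Of 13247 genes tested, 8146 (61.5%) passed the adjusted p threshold of limma, 3416 higher and 4730 lower in IRF8-labelled cells, and 1986 of the rises and 1980 of the falls were at least 2-fold. Log2 fold changes of the experiments correlated at r = 0.958 across genes. Calling selects for equal signs, which every call here and below had. In 535 calls (433 higher, 102 lower) only 1 of the groups was above background, and in 9 neither was. The median change over all genes was -0.13; scaling on spike-in controls moved it to -0.25 and the number of calls to 4623.

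Monocyte and macrophage genes rose as a group. Of 28 monocyte and macrophage markers tested, 19 rose and 3 fell (20 and 3 adjusted over the list alone). Their median was 2.12 (2.70 and 1.82 by experiment, 2.48 with bounds), with camera adjusted p = 4.06e-07. Gpnmb, a glycoprotein of macrophages, rose at least 704-fold, the scavenger receptor gene Msr1 at least 139-fold, and the mannose receptor gene Mrc1 101-fold (SE ≤ 0.33, adjusted p ≤ 2.11e-05). Ly6c1 and Fcgr4 were among those that fell, picked out after values were seen. Pattern recognition, Fc and complement receptor genes numbered 34, of which 30 rose and 3 fell (30 and 3 adjusted over the list alone). Their median was 2.74 (2.78 and 2.70 by experiment, 2.55 with bounds), with adjusted p = 6.75e-11. Clec4n, the C-type lectin dectin-2, rose 2317-fold, the complement receptor gene C3ar1 at least 163-fold and Tlr13, a sensor of bacterial RNA, 213-fold (SE ≤ 0.20, adjusted p ≤ 1.74e-05), while Fcgr4, C5ar1 and C3 fell. Among 36 lysosome and cathepsin genes 28 rose and 2 fell (28 and 2 adjusted over the list alone, 28 and 0 with median scaling). Their median was 1.43 (1.49 and 1.43 by experiment), with adjusted p = 1.85e-09; besides Ctss and Lgmn, the proton pump subunit gene Atp6v0d2 rose at least 248-fold. SE was 0.29 and the adjusted p = 2.95e-05. Acp5 and Neu1 fell. Of 23 chemokine and cytokine genes, 18 rose and 1 fell (18 and 1 adjusted over the list alone). Their median was 2.49 (2.59 and 2.40 by experiment, 2.26 with bounds, 1.23 with normexp), with adjusted p = 8.62e-08. Ccl7 rose at least 161-fold, the costimulatory ligand gene Tnfsf9 at least 118-fold and Ccl6 188-fold (SE ≤ 0.35, adjusted p ≤ 4.63e-05), and Vegfa fell. With an estimated correlation between genes these calls were lost. Adjusted p was then 0.0510 for the monocyte, receptor and chemokine lists and 0.0553 for the lysosome list.

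Genes of antigen presentation and of the interferon response rose too. Of 13 MHC class II genes 12 rose and 0 fell (12 and 0 adjusted over the list alone). Their median was 5.85 (5.74 and 5.95 by experiment, 4.03 with bounds, 3.44 with normexp), with adjusted p = 2.68e-08, and Cd74, the invariant chain of class II molecules, rose 1706-fold (log2 10.74 ± 0.18 (SE), adjusted p = 7.42e-06). Of 17 dendritic cell markers 12 rose and 1 fell (14 and 1 adjusted over the list alone). Their median was 2.996 (3.04 and 3.65 by experiment, 2.01 with bounds, 1.13 with normexp), with adjusted p = 1.65e-06. Ccr7, a chemokine receptor for migration to lymph nodes, rose at least 158-fold, the lectin gene Clec10a 419-fold and the chemokine gene Ccl17 at least 342-fold (SE ≤ 0.18, adjusted p ≤ 1.09e-05); Tcf4 fell. Of 21 MHC class I and peptide loading genes 15 rose and 4 fell (15 and 4 adjusted over the list alone, 11 and 2 with spike-ins). Their median was 1.05 (1.12 and 1.00 by experiment), with adjusted p = 2.91e-04. Tapbp (tapasin) rose 4.03-fold, H2-Q10 2.85-fold and the immunoproteasome gene Psmb9 2.67-fold (SE ≤ 0.11, adjusted p ≤ 2.70e-04), while Tapbpl, Calr, Pdia3 and Canx fell. Of 39 interferon response genes 26 rose and 6 fell (26 and 7 adjusted over the list alone, 21 and 3 with normexp, 18 and 2 with spike-ins). Their median was 0.94 (0.90 and 0.85 by experiment, 0.88 with bounds, 0.54 with normexp), with adjusted p = 7.69e-06. Ifi27l2a rose 41.7-fold, the guanylate-binding protein gene Gbp2 at least 14.6-fold and Oasl2 at least 4.48-fold (SE ≤ 0.59, adjusted p ≤ 0.00200). These list calls were lost with an estimated correlation. Adjusted p was then 0.0510 for MHC class II, 0.0802 for dendritic cells, 0.255 for MHC class I and 0.205 for interferon response.

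Neutrophil, cell cycle and stem cell genes fell. Of 28 neutrophil and granule protein genes 2 rose and 24 fell (2 and 24 adjusted over the list alone). Their median was -3.05 (-3.26 and -2.90 by experiment, -2.97 with bounds), with adjusted p = 4.15e-08; Ltb4r1 and Anxa1 rose. Of 37 cell cycle genes 1 rose and 36 fell (1 and 36 adjusted over the list alone). Their median was -1.28 (-1.30 and -1.26 by experiment), with adjusted p = 2.68e-08. Mcm7, a helicase subunit of DNA replication, fell 3.56-fold, the mitotic kinesin gene Kif11 3.47-fold and Cdc6, which licenses replication origins, 3.26-fold (SE 0.08, adjusted p = 7.84e-05 to 8.32e-05). The member that rose was Ccnd1 (cyclin D1), by at least 779.5-fold (log2 10.82 ± 0.39 (SE), adjusted p = 4.32e-05). Of 17 stem and progenitor genes 2 rose and 11 fell (3 and 11 adjusted over the list alone). Their median was -0.83 (-0.78 and -0.87 by experiment), with adjusted p = 0.0229. The stem cell antigen gene Prom1 fell 14.4-fold, the progenitor transcription factor gene Myb 6.32-fold and Spn (CD43) 4.52-fold (SE ≤ 0.17, adjusted p ≤ 7.43e-05). Runx1 rose, and Cd34 rose at least 4.37-fold (adjusted p = 4.73e-04; 0.0501 with normexp). With an estimated correlation these list calls were lost (adjusted p = 0.171 for the neutrophil list, 0.213 for cell cycle and 0.293 for stem genes).

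Myeloid transcription factors and apoptosis genes were higher on balance. Of 42 myeloid transcription factor genes 29 rose and 8 fell (30 and 9 adjusted over the list alone). Their median was 1.23 (1.26 and 1.20 by experiment), with adjusted p = 5.06e-06, and 0.171 with an estimated correlation. Irf5, a transcription factor of inflammatory signalling, rose 133-fold (log2 7.06 ± 0.20 (SE)), and the early response genes Atf3 and Egr1 and the repressor gene Bcl6 rose 318-fold, 133-fold and 221-fold, each with 1 of the 2 control arrays above background. SE reached 0.30 and adjusted p 4.88e-05. Of 30 apoptosis genes 14 rose and 5 fell (15 and 5 adjusted over the list alone, 10 and 0 with spike-ins). Their median was 0.43 (0.46 and 0.41 by experiment), with adjusted p = 0.00751, and 0.329 with an estimated correlation. Trp53inp1, a target of p53, rose 5.97-fold, the cell cycle inhibitor gene Cdkn1a 4.40-fold and the survival gene Bcl2a1d 3.55-fold (SE ≤ 0.12, adjusted p ≤ 1.03e-04), and Bcl2l2, Bid and Casp4 were among those that fell.

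5 lists did not pass. Of 13 basophil, mast cell and eosinophil markers 4 rose and 4 fell (4 and 4 adjusted over the list alone): Il1rl1, the receptor for interleukin-33, rose at least 99.4-fold and the prostaglandin synthase gene Hpgds at least 8.21-fold, while the basophil protease gene Mcpt8 fell 20.2-fold. SE reached 0.42 and adjusted p 8.28e-04. Of 10 lymphocyte markers 2 rose and 5 fell (2 and 5 adjusted over the list alone, 2 and 3 with normexp), with the interleukin-7 receptor gene Il7r at least 171-fold and the adaptor gene Blnk at least 27.3-fold higher and the kinase gene Lck 7.61-fold lower. SE reached 0.20 and adjusted p 2.20e-04. Of 11 erythroid and megakaryocyte markers 3 rose and 4 fell (3 and 4 adjusted over the list alone); the transferrin receptor gene Tfrc fell 5.17-fold and Epor 4.79-fold. SE was 0.10 and adjusted p reached 6.35e-05. Of 7 fibroblast and packaging cell markers 4 rose and 1 fell (4 and 2 adjusted over the list alone, 2 and 1 with spike-ins), with the filament gene Vim 5.63-fold and the smooth muscle actin gene Acta2 3.12-fold higher. SE was 0.14 and adjusted p reached 4.99e-04. Of 18 heat shock and unfolded protein response genes 3 rose and 10 fell (3 and 10 adjusted over the list alone, 1 and 4 with spike-ins); Asns fell 2.65-fold and the chaperone gene Hsp90aa1 2.20-fold, while the stress gene Ddit3 rose 2.18-fold. SE reached 0.13 and adjusted p 0.00138. The medians of these lists were -0.21, -0.59, 0.04, 0.59 and -0.42, and camera adjusted p ran from 0.173 to 0.959. The first was 0.02 with bounds, -0.07 with normexp and -0.34 with spike-ins, and the fourth 0.24 with normexp. The mean of the basophil list was 0.05 and that of the lymphocyte list 0.50, opposite in sign to their medians; camera put the erythroid list down against a positive mean of 0.37, and its median was -0.01, -0.06 and -0.09 with quantile normalization, normexp and spike-in scaling.

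The rule for named genes also took Epx, which fell 11.5-fold with 1 of the 2 IRF8-labelled arrays above background, and Oasl1, Ctsk, Vwf, Hba-a2 and Col1a2, which rose 40.5-fold, 137-fold, 63.0-fold, 8.60-fold and 1.64-fold with 1 of the 2 control arrays above background. H2-D1 and Bmf rose 2.58-fold and 4.14-fold, and Igll1, Thy1 and Chac1 fell at least 2.59-fold, 1.70-fold and 2.99-fold (SE ≤ 0.47, adjusted p ≤ 0.0291). Igll1, Thy1 and Col1a2 lost the call with normexp (adjusted p = 0.0947 to 0.562), Thy1 without control replicate 2 (0.0829), IRF8 replicate 2 (0.117) or either KLF4 array (0.0545), and Col1a2 without IRF8 replicate 1 (0.0556).

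The comparison of KLF4-labelled cells with control asked the same of KLF4. These cells also gained transcripts of macrophages, receptors, chemokines and lysosomes, and 104 genes fell at least 2-fold. Wfdc17 rose 7964-fold and the osteocalcin family genes Bglap2 and Bglap3 rose 3597-fold and 1526-fold, each with 1 of the 2 control arrays above background. SE reached 0.25 and adjusted p 3.02e-05. Clec4n (dectin-2) rose 1169-fold, Ctss (cathepsin S) at least 604-fold, Gpnmb at least 479.5-fold and Ahnak at least 448-fold (SE ≤ 0.33, adjusted p ≤ 7.21e-05). Emp1, an epithelial membrane protein, rose at least 212-fold, the complement factor gene Cfb at least 168-fold and Mall, a membrane traffic protein, at least 151-fold. SE reached 0.40 and adjusted p 1.98e-04. Fcnb fell 10.8-fold (log2 -3.43 ± 0.12 (SE), adjusted p = 1.27e-04).

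Other deep falls were of genes that were not well above background on either KLF4-labelled array. Gadl1, Fscn2 and Etl4 fell at least 6.42-fold, at least 3.50-fold and at least 2.69-fold (SE ≤ 0.53, adjusted p ≤ 0.00551), and lost the call with normexp (adjusted p = 0.0733 to 0.138). Tcerg1l, Sult2a3, Mc3r, Yap1 and Zfp583 fell at least 4.36-fold, at least 6.14-fold, at least 3.60-fold, at least 3.25-fold and at least 3.18-fold (SE ≤ 0.94, adjusted p ≤ 0.0446). All 5 lost the call with normexp (adjusted p = 0.145 to 0.221), without KLF4 replicate 1 (0.0527 to 0.137) and without KLF4 replicate 2 (0.0718 to 0.182). The first 4 of these lost it without IRF8 replicate 1 or 2 (0.0531 to 0.0747 each), Sult2a3 and Mc3r without control replicate 1 (0.115 and 0.0538), and Yap1 with quantile normalization (0.0509).

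Of the 13247 genes, 2544 (19.2%) passed limma's threshold, 1372 higher and 1172 lower, and 851 of the rises and 104 of the falls were at least 2-fold. The experiments correlated at r = 0.901 across genes, and in 278 calls (255 higher, 23 lower) only 1 group was above background. With the block 6744 passed, 2188 higher and 4556 lower, and 888 and 115 at 2-fold or more. Falls and list medians take no account of the median over all genes, -0.16 (median blocked SE 0.06). Normexp gave 788 higher and 264 lower, spike-in scaling 793 and 94, and quantile normalization 1558 and 768. Leaving out 1 array lowered the rises and falls to 923/262 and 1117/294 (control replicate 1, 2), 1109/388 (either IRF8 array) and 774/141 and 771/110 (KLF4 replicate 1, 2), and moved the falls of at least 2-fold to 163 without control replicate 2 and 66 without KLF4 replicate 2.

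Macrophage, receptor, chemokine and lysosome genes rose as groups. Of 28 monocyte and macrophage markers 19 rose and 1 fell (21 and 1 adjusted over the list alone). Their median was 2.39 (2.43 and 2.29 by experiment, 1.81 with bounds, 1.57 with normexp), with camera adjusted p = 9.78e-17. Beside Gpnmb, the receptor gene Cd300e rose at least 25.8-fold, the fractalkine receptor gene Cx3cr1 at least 37.6-fold and Msr1 at least 14.02-fold (SE ≤ 0.43, adjusted p ≤ 0.00117); F13a1 fell. Of 34 pattern recognition, Fc and complement receptor genes 24 rose and 0 fell (27 and 0 adjusted over the list alone). Their median was 1.41 (1.52 and 1.29 by experiment, 1.52 with bounds), with adjusted p = 1.04e-21. Tlr13 rose 96.0-fold and C3ar1 at least 39.6-fold (SE ≤ 0.20, adjusted p ≤ 7.72e-05). Of 23 chemokine and cytokine genes 16 rose and 1 fell (17 and 1 adjusted over the list alone). Their median was 2.18 (1.72 and 2.04 by experiment, 1.59 with bounds, 0.96 with normexp), with adjusted p = 5.46e-14. Ccl6 rose 143-fold, Ccl2 at least 45.7-fold and the inflammasome substrate gene Il18 at least 45.1-fold (SE ≤ 0.28, adjusted p ≤ 1.53e-04), and Ccl12, called lower, was not above background in either group. Of 36 lysosome and cathepsin genes 22 rose and 0 fell (24 and 0 adjusted over the list alone, 25 and 2 with the block, 11 and 0 with spike-ins). Their median was 0.64 (0.69 and 0.53 by experiment), with adjusted p = 9.16e-14; Lgmn rose at least 86.4-fold and Atp6v0d2 at least 128-fold. SE reached 0.33 and adjusted p 1.54e-04. These 4 lists also passed with an estimated correlation: adjusted p = 0.02003 for the first 3 and 0.0413 for the lysosome list.

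Of 13 MHC class II genes 4 rose and 0 fell (7 and 0 adjusted over the list alone, with the block or quantile normalization). Their median was 0.45 (0.38 and 0.46 by experiment, 0.43 with bounds) and mean 1.55. Adjusted p was 1.55e-05, and 0.0811 with an estimated correlation. The 4 that rose were Ctss (also in the lysosome list), H2-DMa, Cd74 and H2-Eb2. Cd74 rose 5.26-fold (log2 2.40 ± 0.18 (SE), adjusted p = 0.00117) and H2-Eb2 5.48-fold, with 1 of the 2 control arrays above background. Of the list, 3 members were below background in both groups, and no test left out Ctss. MHC class I and peptide loading genes did not pass (adjusted p = 0.0687; 0.0199 with normexp or over genes above background on all 6 arrays): of 21, 5 rose and 2 fell (7 and 4 adjusted over the list alone, 7 and 6 with the block, 5 and 0 with normexp, 0 and 0 with spike-ins). Their median was 0.07 (0.15 and 0.06 by experiment, 0.17 with quantile normalization); Tapbpl and Pdia3 fell. The class I genes H2-D1 and H2-T23 rose 1.63-fold and 1.56-fold (SE ≤ 0.10, adjusted p ≤ 0.0114), and lost the call without control replicate 1 (adjusted p = 0.0569 to 0.0586), KLF4 replicate 1 (0.0552 to 0.0672) or KLF4 replicate 2 (0.0807 to 0.0821). Of 39 interferon response genes 14 rose and 1 fell (15 and 1 adjusted over the list alone, 5 and 0 with normexp, 8 and 0 with spike-ins). Their median was 0.42 (0.41 and 0.35 by experiment, 0.20 with bounds, 0.14 with normexp). Adjusted p was 9.14e-07, and 0.208 with an estimated correlation. The antiviral gene Oas2 rose 16.2-fold and the nucleic acid sensor gene Zbp1 11.2-fold (SE ≤ 0.15, adjusted p ≤ 2.12e-04), and Ifit2 fell. Dendritic cell markers did not pass (adjusted p = 0.595): of 17, 3 rose and 2 fell (3 and 4 adjusted over the list alone, 3 and 6 with the block, 3 and 0 with spike-ins). Their median was -0.33 (-0.25 and -0.36 by experiment, -0.31 with bounds, -0.03 with quantile normalization) and a mean of 0.36. Itgax rose at least 14.9-fold, the transcription factor gene Batf3 8.04-fold and Clec10a 4.30-fold (SE ≤ 0.23, adjusted p ≤ 7.69e-04).

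Of 42 myeloid transcription factor genes 20 rose and 3 fell (22 and 6 adjusted over the list alone, 23 and 6 with the block, 14 and 1 with normexp, 17 and 0 with spike-ins). Their median was 0.58 (0.56 and 0.50 by experiment, 0.32 with bounds, 0.37 with normexp). Adjusted p was 4.91e-08, and 0.130 with an estimated correlation. The orphan receptor gene Nr4a1 rose 9.17-fold (log2 3.20 ± 0.12 (SE)), and Atf3 and Egr1 48.8-fold and 7.79-fold with 1 of the 2 control arrays above background (SE ≤ 0.23, adjusted p ≤ 1.87e-04), while Cebpe, Id2 and Hhex fell. Of 37 cell cycle genes 1 rose and 11 fell (1 and 20 adjusted over the list alone, 1 and 32 with the block, 1 and 5 with quantile normalization, 1 and 1 with normexp, 1 and 0 with spike-ins). Their median was -0.34 (-0.34 and -0.37 by experiment), with adjusted p = 1.41e-04, and 0.352 with an estimated correlation. The member that rose was Ccnd1, by at least 10.3-fold (log2 4.58 ± 0.39 (SE), adjusted p = 0.00203). Mcm7 fell 1.46-fold (log2 -0.55 ± 0.08 (SE), adjusted p = 0.0155) and lost the call without control replicate 1 (adjusted p = 0.0724) or 2 (0.0707) or KLF4 replicate 1 (0.0763) or 2 (0.105). Of 17 stem and progenitor genes 0 rose and 5 fell (0 and 8 adjusted over the list alone, 0 and 13 with the block, 0 and 2 with normexp, 0 and 0 with spike-ins). Their median was -0.39 (-0.42 and -0.44 by experiment, -0.41 with bounds), with adjusted p = 0.00405, and 0.244 with an estimated correlation. Lmo2 and Runx1, transcriptional regulators of blood progenitors, fell 1.56-fold and 1.51-fold (SE ≤ 0.10, adjusted p ≤ 0.0171); both lost the call without control replicate 2 (adjusted p = 0.0615 to 0.0763), KLF4 replicate 1 (0.0763 to 0.0833) or KLF4 replicate 2 (0.0909 to 0.110), and Runx1 without control replicate 1 (0.0724).

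Of 28 neutrophil and granule protein genes 4 rose and 9 fell (4 and 12 adjusted over the list alone, 4 and 15 with the block, 2 and 9 with normexp, 3 and 4 with spike-ins). Their median was -0.40 (-0.38 and -0.41 by experiment, -0.25 with quantile normalization). Beside Fcnb, the surface glycoprotein gene Ceacam10 fell 4.05-fold, and Anxa1, the anti-inflammatory annexin, rose 9.31-fold (SE ≤ 0.16, adjusted p ≤ 0.00158), as did Mmp9, Ltb4r1 and Stfa3. The list's call (adjusted p = 0.0465, and adjusted p = 0.483 with an estimated correlation) was lost with the block (0.105), with median scaling (0.0645), over genes above background on all 6 arrays (0.150), and without control replicate 1 (0.185) or KLF4 replicate 2 (0.0999). Of 30 apoptosis genes 7 rose and 1 fell (7 and 1 adjusted over the list alone, 10 and 7 with the block, 2 and 0 with spike-ins). Their median was 0.06 (0.03 and 0.05 by experiment). The death receptor gene Fas rose 4.11-fold, Bcl2a1d 2.25-fold and Birc3 1.87-fold (SE ≤ 0.15, adjusted p ≤ 0.00440). This call (adjusted p = 0.0242, and adjusted p = 0.403 with an estimated correlation) was lost without control replicate 1 (0.0811) or KLF4 replicate 2 (0.0774), with spike-in scaling (0.217) and by fry (0.0559). Of 7 fibroblast and packaging cell markers 3 rose and 0 fell (3 and 1 adjusted over the list alone, 1 and 0 with spike-ins). Their median was 0.21 (0.40 and 0.01 by experiment, 0.32 with quantile normalization, -0.02 with normexp); Thy1, a surface glycoprotein of fibroblasts and T cells, rose 21.6-fold (log2 4.43 ± 0.22 (SE), adjusted p = 3.09e-04). That call (adjusted p = 0.0485, and adjusted p = 0.321 with an estimated correlation) was lost with the block (0.0518), without control replicate 1 (0.0566), control replicate 2 (0.0762) or KLF4 replicate 1 (0.183), and with median (0.0513) or spike-in scaling (0.0867). Of 18 heat shock and unfolded protein response genes 0 rose and 6 fell (0 and 6 adjusted over the list alone, 1 and 14 with the block, 0 and 0 with normexp, 0 and 0 with spike-ins). Their median was -0.32 (-0.25 and -0.40 by experiment, -0.17 with quantile normalization), with adjusted p = 0.0122, and adjusted p = 0.244 with an estimated correlation (0.0834 by camera with spike-in scaling).

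Among heat shock and unfolded protein response genes the stress genes Ddit3 and Sesn2 fell 1.44-fold and 1.39-fold (SE ≤ 0.09, adjusted p ≤ 0.0237). Both lost the call with normexp (adjusted p = 0.0571 to 0.0727), without control replicate 1 (0.0716 to 0.101) or 2 (0.0650 to 0.0833) and without KLF4 replicate 1 (0.0809 to 0.118) or 2 (0.0978 to 0.120), and Sesn2 without either IRF8 array (0.0580). Basophil, mast cell and eosinophil markers did not pass (adjusted p = 0.114; 0.0245 with spike-in scaling): of 13, 4 rose and 2 fell (4 and 2 adjusted over the list alone, 2 and 1 with normexp). Their median was 0.34 (0.53 and -0.36 by experiment, 0.17 with bounds, -0.20 with normexp). Ear2, an eosinophil ribonuclease gene, rose 16.3-fold with 1 of the 2 control arrays above background and the mast cell tryptase gene Tpsb2 4.86-fold (SE ≤ 0.26, adjusted p ≤ 0.00218). Of 10 lymphocyte markers 2 rose and 4 fell (2 and 5 adjusted over the list alone, 1 and 1 with normexp, 2 and 1 with spike-ins). Their median was -0.40 (-0.28 and -0.52 by experiment, -0.56 with bounds) against a mean of 0.15 (adjusted p = 0.659); Il7r rose at least 21.2-fold (log2 5.25 ± 0.12 (SE), adjusted p = 3.75e-05). Of 11 erythroid and megakaryocyte markers 2 rose and 1 fell (2 and 2 adjusted over the list alone). Their median was 0.02 (0.22 and -0.15 by experiment, 0.13 with quantile normalization, -0.13 with normexp) (adjusted p = 0.304). Vwf, the von Willebrand factor gene of platelets and endothelium, rose 220.4-fold with 1 of the 2 control arrays above background (log2 7.78 ± 0.47 (SE), adjusted p = 6.30e-04).

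The rule also took Ctsk and Bcl6, which rose 75.3-fold and 16.9-fold with 1 of the 2 control arrays above background, and Il1b, which rose at least 14.4-fold. SE reached 0.40 and adjusted p 0.00115. Il1rl1, Xaf1 and Gbp2 rose at least 1.84-fold, at least 4.82-fold and at least 2.77-fold (SE ≤ 0.36, adjusted p ≤ 0.00799) and lost the call with normexp (adjusted p = 0.0632 to 0.274), and Blnk was above background in neither group. Prg2, H2-DMa, B2m, H2-Q7, Bmf, Car2, Vim and Acta2 rose at least 1.64-fold, 1.34-fold, 1.76-fold, 1.55-fold, 2.22-fold, 1.61-fold, 1.73-fold and 1.65-fold (SE ≤ 0.30, adjusted p ≤ 0.0345). Ltf, Tcf4, Prom1, Myb, Tyms, Mcm4, Igll1, Cd3d, Tfrc, Herpud1 and Asns fell 6.36-fold, 1.62-fold, 1.90-fold, 1.40-fold, 1.47-fold, 1.37-fold, at least 2.66-fold, 1.99-fold, 1.66-fold, 1.51-fold and 1.47-fold. SE reached 0.37 and adjusted p 0.0361. These 19 genes all lost the call without KLF4 replicate 2 (adjusted p = 0.0530 to 0.159), and all but Tcf4 without KLF4 replicate 1 (0.0726 to 0.147). All but Ltf, Tcf4, Prom1, Cd3d and Tfrc lost it without control replicate 1 (0.0524 to 0.102), and H2-DMa, Vim and all that fell but Ltf and Tcf4 without control replicate 2 (0.0501 to 0.142). H2-DMa, Acta2, Myb, Mcm4, Herpud1 and Asns lost it without either IRF8 array (0.0518 to 0.0845), the same genes and Prg2, Prom1, Tyms, Igll1 and Cd3d with normexp (0.0574 to 0.522), and Mcm4 and Cd3d with quantile normalization (0.0586 to 0.0616).

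The direct comparison of IRF8-labelled with KLF4-labelled cells tested where the responses differed. Antigen presentation and dendritic cell genes were higher in IRF8-labelled cells, and neutrophil and cell cycle genes were lower. These list calls were lost with an estimated correlation (adjusted p = 0.103 to 0.331). Tgfbi was at least 2248-fold higher, H2-Eb1 at least 1567-fold, H2-Aa at least 289-fold, H2-Ab1 1166-fold and Cd74 324-fold (SE ≤ 0.69, adjusted p ≤ 4.69e-04). Ccl17 was at least 471-fold higher, Ccr7 at least 203-fold, the ganglioside synthase gene St3gal5 900.0-fold, the reticulon gene Rtn1 at least 217-fold and Plbd1 at least 164-fold. SE reached 0.37 and adjusted p 1.34e-04. In the other direction, Mall was at least 189-fold higher in KLF4-labelled cells, Bglap2 469-fold, Bglap3 363-fold, the stefin gene Stfa3 68.9-fold and the transglutaminase gene Tgm2 62.8-fold. SE reached 0.40 and adjusted p 1.65e-04. Krtdap, a gene of keratinocyte differentiation, was at least 23.8-fold higher there, the anaphylatoxin receptor gene C5ar1 at least 22.4-fold, Ambp at least 19.0-fold, the carbonic anhydrase gene Car6 at least 33.8-fold, and Cfb 147-fold with 1 of the 2 IRF8-labelled arrays above background. SE reached 0.38 and adjusted p 4.01e-04.

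Of the 13247 genes, 6695 (50.5%) passed limma's threshold, 3141 higher and 3554 lower in IRF8-labelled cells, and 1336 and 1240 differed by at least 2-fold. The experiments correlated at r = 0.950 across genes, and in 320 calls only 1 group was above background. Scaling on spike-in controls moved the median over all genes from -0.01 to -0.17 and the number of calls to 2719.

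Of 13 MHC class II genes 10 were higher in IRF8-labelled cells and 1 was lower (10 and 1 adjusted over the list alone). Their median was 3.76 (3.87 and 3.77 by experiment), with adjusted p = 6.46e-07; the lower member was H2-Eb2. Of 17 dendritic cell markers 13 were higher and 0 were lower (15 and 0 adjusted over the list alone). Their median was 2.87 (2.87 and 2.90 by experiment, 2.62 with bounds, 1.31 with normexp), with adjusted p = 3.16e-08; the maturation gene Cd83 was at least 34.0-fold higher and Clec10a 97.4-fold. SE reached 0.35 and adjusted p 2.11e-04. Of 21 MHC class I and peptide loading genes 15 were higher and 1 was lower (16 and 2 adjusted over the list alone, 16 and 3 with the block, 6 and 0 with spike-ins). Their median was 0.64 (0.63 and 0.63 by experiment), with adjusted p = 2.86e-04. Tapbp was 3.05-fold higher, Nlrc5, an activator of class I genes, 2.65-fold and the immunoproteasome gene Psmb8 2.57-fold (SE ≤ 0.15, adjusted p ≤ 0.00170), and Tapbpl was lower. Of 39 interferon response genes 20 were higher and 5 were lower (21 and 8 adjusted over the list alone, 23 and 10 with the block, 21 and 8 with quantile normalization, 22 and 8 with median scaling, 9 and 3 with spike-ins). Their median was 0.54 (0.51 and 0.56 by experiment), with adjusted p = 0.00442. Oasl2 was at least 5.75-fold higher and Ifi27l2a 11.03-fold, while Oas2 was 9.17-fold lower (SE ≤ 0.59, adjusted p ≤ 0.00476), together with Ifit2, Isg20, Irf1 and Cmpk2. With an estimated correlation these calls were lost. Adjusted p was then 0.103 for MHC class II and dendritic cells, 0.331 for MHC class I and 0.335 for interferon response.

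Of 36 lysosome and cathepsin genes 25 were higher in IRF8-labelled cells and 2 were lower (25 and 2 adjusted over the list alone, 11 and 1 with spike-ins). Their median was 0.81 (0.80 and 0.80 by experiment), with adjusted p = 1.52e-06; Ctsh (cathepsin H) was 65.9-fold higher, Lgmn 14.5-fold and Ctss 13.3-fold (SE ≤ 0.33, adjusted p ≤ 8.50e-04), and Acp5 and Neu1 were lower. Of 34 receptor genes 25 were higher and 6 were lower (26 and 6 adjusted over the list alone, 14 and 4 with spike-ins). Their median was 1.00 (1.04 and 0.96 by experiment), with adjusted p = 2.53e-05. Itgax was 62.4-fold higher and the complement gene C1qc at least 13.5-fold (SE ≤ 0.36, adjusted p ≤ 3.72e-04). Of 42 transcription factor genes 22 were higher and 10 were lower (23 and 11 adjusted over the list alone, 14 and 7 with spike-ins). Their median was 0.41 (0.47 and 0.39 by experiment, 0.26 with spike-ins), with adjusted p = 0.0106 (0.0855 over genes above background on all 6 arrays); Irf5 was 27.8-fold higher, Egr2 21.6-fold and the repressor gene Prdm1 at least 4.86-fold. SE reached 0.24 and adjusted p 3.24e-04. Of 30 apoptosis genes 14 were higher and 4 were lower (14 and 4 adjusted over the list alone, 5 and 2 with spike-ins). Their median was 0.25 (0.25 and 0.29 by experiment, 0.09 with spike-ins), with adjusted p = 0.0142 (0.0600 with spike-in scaling); Trp53inp1 was 4.14-fold higher and the p53 target gene Bbc3 4.01-fold (SE ≤ 0.14, adjusted p ≤ 5.09e-04), and Bcl2l2, Bid, Casp4 and Fas were lower. Of 28 neutrophil genes 2 were higher and 24 were lower (2 and 24 adjusted over the list alone, 0 and 24 with spike-ins). Their median was -2.76 (-2.89 and -2.64 by experiment), with adjusted p = 9.95e-10. Ngp was 55.2-fold lower and Stfa2 52.9-fold (SE 0.10, adjusted p = 2.86e-05), and Ltb4r1 and Anxa1 were higher. Of 37 cell cycle genes 1 was higher and 32 were lower (1 and 33 adjusted over the list alone, 1 and 21 with spike-ins). Their median was -0.89 (-0.93 and -0.86 by experiment), with adjusted p = 4.49e-09. Ccnd1 was 75.9-fold higher, while Kif11 was 2.59-fold lower and the mitotic kinase gene Plk1 2.53-fold (SE ≤ 0.39, adjusted p ≤ 7.72e-04). With an estimated correlation the calls were lost, at adjusted p = 0.128 for lysosomes and 0.103 for receptors, whose estimate lay below 0.01. Adjusted p was 0.335 for transcription factors and apoptosis genes, 0.198 for neutrophil genes and 0.268 for the cell cycle.

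8 lists did not pass in the direct comparison. Of 28 monocyte markers 15 were higher in IRF8-labelled cells and 9 lower (15 and 9 adjusted over the list alone, 9 and 9 with spike-ins). Their median was 0.91 (0.91 and 0.82 by experiment). Fcgr1, the high-affinity antibody receptor gene, was 29.9-fold higher and Mrc1 19.2-fold (SE ≤ 0.10, adjusted p ≤ 3.22e-05), and Cd300e was 37.1-fold lower with 1 of the 2 IRF8-labelled arrays above background (adjusted p = 7.60e-04). The list's adjusted p of 0.0537 passed without either control array (0.0404 each), IRF8 replicate 2 (0.0429) or KLF4 replicate 2 (0.0442), with quantile normalization (0.0440) spike-in scaling (0.0367) or normexp (0.0131), and over genes above background on all 6 arrays (0.0103). Of 17 stem and progenitor genes 3 were higher and 9 lower (3 and 9 adjusted over the list alone, 1 and 9 with normexp). Their median was -0.52 (-0.54 and -0.50 by experiment). Prom1 was 7.61-fold lower, Myb 4.52-fold and Myc 4.09-fold (SE ≤ 0.17, adjusted p ≤ 5.59e-04), and Cd34, Flt3 and Runx1 were higher, Cd34 without the call with normexp (adjusted p = 0.05001). This list's adjusted p of 0.0537 was 0.0457 with the block, 0.0442 without KLF4 replicate 2, 0.0131 with normexp and 0.00847 over genes above background on all 6 arrays. Of 23 chemokine and cytokine genes 10 were higher and 6 lower (10 and 7 adjusted over the list alone, 9 and 3 with normexp, 6 and 5 with spike-ins). Their median was 0.16 (0.28 and 0.03 by experiment, -0.00 with spike-ins); Ccl12 was at least 21.3-fold higher, Ccl7 46.7-fold and Ccl2 31.0-fold. SE reached 0.35 and adjusted p 3.76e-04. Of 13 basophil, mast cell and eosinophil markers 3 were higher and 7 lower (3 and 8 adjusted over the list alone). Their median was -1.53 (-1.73 and -1.33 by experiment, -1.03 with bounds, -0.61 with normexp), with adjusted p = 0.142 (0.0285 over genes above background on all 6 arrays); Il1rl1 was 54.1-fold higher and Mcpt8 7.85-fold lower. SE reached 0.26 and adjusted p 1.89e-04.

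Of 10 lymphocyte markers 2 were higher in IRF8-labelled cells and 4 lower (2 and 4 adjusted over the list alone, 2 and 1 with normexp). Their median was 0.07 (0.06 and -0.09 by experiment, 0.31 with bounds, -0.03 with quantile normalization, -0.09 with spike-ins); Blnk was at least 35.0-fold higher and Il7r 8.10-fold. SE reached 0.14 and adjusted p 1.38e-04. Of 11 erythroid and megakaryocyte markers 2 were higher and 4 lower (2 and 4 adjusted over the list alone), with Epor 3.67-fold and the carbonic anhydrase gene Car2 3.63-fold lower. SE reached 0.13 and adjusted p 5.23e-04. Of 7 fibroblast and packaging cell markers 4 were higher and 1 lower (4 and 1 adjusted over the list alone, 1 and 1 with spike-ins), with Vim 3.25-fold and Tagln 2.03-fold higher and Thy1 36.7-fold lower (SE ≤ 0.22, adjusted p ≤ 0.00237); the median was 0.51 (0.26 with normexp) and the mean -0.23. Of 18 heat shock and unfolded protein response genes 3 were higher and 5 lower (3 and 5 adjusted over the list alone, 2 and 2 with spike-ins), with Ddit3 3.15-fold and Sesn2 2.26-fold higher and Asns 1.81-fold lower. SE reached 0.12 and adjusted p 0.00359. Camera adjusted p for the chemokine, lymphocyte, erythroid, fibroblast and heat shock lists ran from 0.270 to 0.874.

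The rule also took Itgb2l and Ear2, 47.0-fold and 18.9-fold lower with 1 of the 2 IRF8-labelled arrays above background, and Oasl1, 45.4-fold higher with 1 of the 2 KLF4-labelled arrays above background. Hpgds was at least 10.5-fold higher, and Psmb9, Psap, Cdkn1a, Bcl2l1, Hba-a2 and Acta2 were 2.44-fold, 6.80-fold, 2.96-fold, 2.84-fold, 5.02-fold and 1.89-fold higher in IRF8-labelled cells. Il12a was at least 3.56-fold lower, and Mcm2, Lck, Vwf and Chac1 were 2.53-fold, 4.89-fold, 3.50-fold and 2.45-fold lower (SE ≤ 0.92, adjusted p ≤ 0.0281). Igll1 was below background in both. Il12a lost the call with normexp (adjusted p = 0.0521), Il12a and Vwf without IRF8 replicate 1 (0.0514 to 0.0986) or 2 (0.0755 to 0.0765), Hba-a2 and Vwf without KLF4 replicate 1 (0.05001 to 0.0921), and Il12a, Vwf and Chac1 without KLF4 replicate 2 (0.0686 to 0.113).

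**Figure D2:**
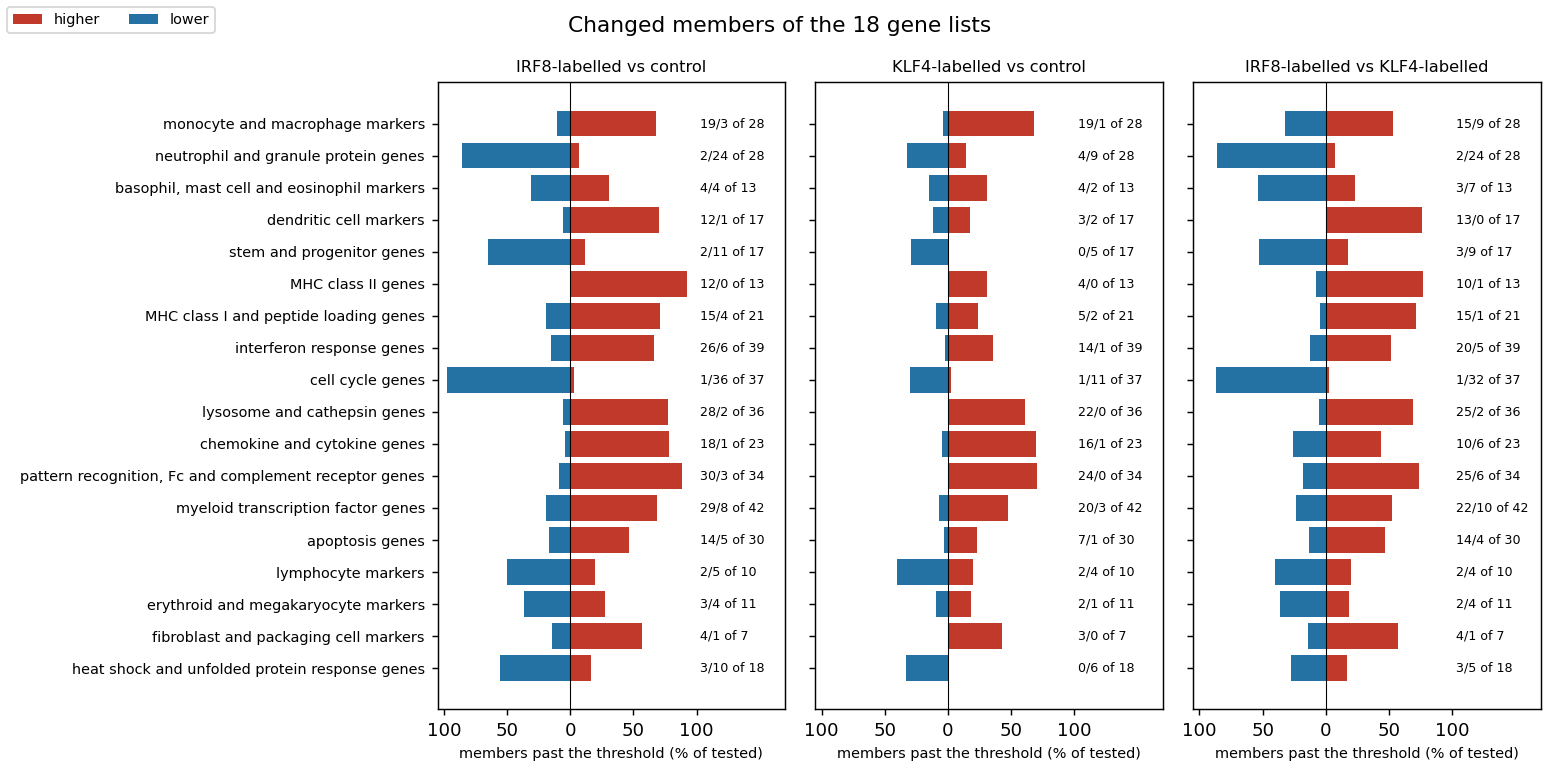
Share of the tested members of each of the 18 gene lists that passed the threshold, in percent (horizontal axis), higher to the right and lower to the left of 0, for the 3 comparisons by label; the figures at the right of each panel give higher and lower counts of the members tested. MHC class II and dendritic cell bars lie mostly to the right in the comparisons with IRF8-labelled cells in first place, and neutrophil and cell cycle bars mostly to the left.

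Against control, 1183 genes, among them Ctss, Gpnmb, Ahnak and Clec4n, rose in both IRF8-labelled and KLF4-labelled cells, and 999, Fcnb among them, fell in both. The opposite moves were fewer: 67 genes rose in IRF8-labelled and fell in KLF4-labelled cells, and 59 did the reverse. Of the genes raised in KLF4-labelled cells, 86.2% were also raised in IRF8-labelled cells, and 34.6% the other way round. The adjustment lets smaller changes pass where more genes change, so these shares rest on unlike cuts. By the direct test, 803 of the 1372 genes raised in KLF4-labelled cells were higher still in IRF8-labelled cells and 290 were lower. Of 2166 genes raised in IRF8-labelled cells and not called in KLF4-labelled cells, 1827 differed by that test. Both comparisons used the same control arrays: independent lists of these sizes would share 354 rises, 418 falls, and 302 and 489.9 opposite moves. The covariance of the log2 fold changes was 1.02 against 0.0227 in simulated unchanged groups with shared controls. Fold changes taken from different experiments, which share no array, had covariances of 0.991 and 0.975. The 2 control arrays cannot be split into parts of 2, so part of the excess of shared calls may come from the shared controls.

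The number of genes changed the same way in both, 2182, was 5649 (1881 rises and 3768 falls) with the block. Shared rises and falls were 690 and 236 with normexp, 638 and 75 with spike-in scaling and 1338 and 649 with quantile normalization. Leaving out 1 array changed the number and its share of rises, 54.2%, to 1007 (79.3%) and 1232 (80.7%) (control replicate 1, 2), 1270 (74.7%) and 1252 (74.7%) (IRF8) and 793 (86.5%) and 767 (88.3%) (KLF4).

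**Figure D3:**
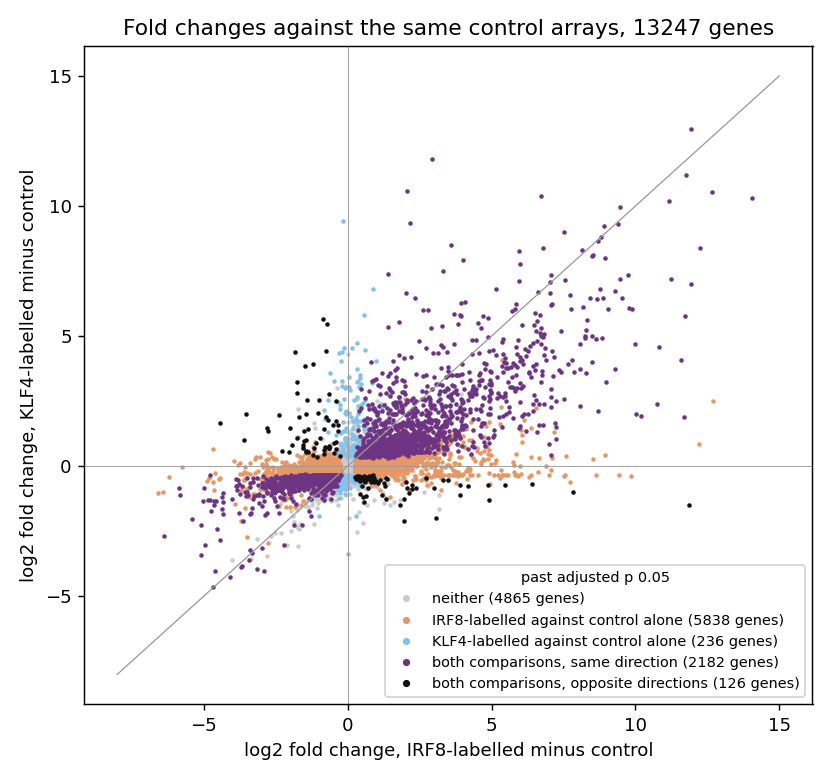
Log2 fold change against the shared control arrays for each of 13247 genes, IRF8-labelled cells on the horizontal and KLF4-labelled cells on the vertical axis, with the line of equal change; colours mark genes past the threshold in neither comparison, in 1 alone, or in both in the same or opposite directions. Most genes called in both lie in the upper right or lower left part.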

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

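The tests of the opposite moves over genes above background on all 6 arrays, and the counts of unnamed probes, were chosen after the first results were seen.

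Some genes were called in opposite directions in the transduced groups, each against the same control arrays, so that a difference between those groups follows from the choice and is no further evidence. There were 67 that rose in IRF8-labelled and fell in KLF4-labelled cells; 54 of them were above background on all 6 arrays, and 3 of these moved at least 2-fold each way. Rgs18, a regulator of G protein signalling in blood cells, had log2 changes against control of 1.96 and -2.12, and Serpinf1, a secreted serpin, of 1.97 and -1.26. Another 59 fell in IRF8-labelled and rose in KLF4-labelled cells; 40 were above background on all 6 arrays and 8 of these moved at least 2-fold each way. Stfa3, a stefin of neutrophils, had log2 changes of -4.43 and 1.67, Tmem119, a membrane protein of bone and microglia, of -3.60 and 1.01, Ffar2, a receptor for short-chain fatty acids, of -2.80 and 1.47, and Ly6a, the stem cell antigen Sca-1, of -1.70 and 1.90. These 6 genes were chosen after their values were seen.

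Probes with no gene name, which no comparison of genes used, also changed. Of 11976 such probes tested with limma, 1591 were higher and 2290 lower in IRF8-labelled cells than in control, and 347 were higher and 139 lower in KLF4-labelled cells than in control. Of 6101 probes named by a genome region, 830 were higher and 1023 lower in IRF8-labelled cells and 149 higher and 76 lower in KLF4-labelled cells, against control.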

How the results depend on the processing

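Settings chosen after the data had been seen, spike-in scaling among them, were listed with the processing. The others were planned.

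Of the single genes named, over all alternatives, 2216 combinations of gene, comparison and setting kept their direction and side of the threshold, 178 lost the call, 8 gained it and 1 turned in direction. Of the gene lists, 677 combinations kept both, 50 lost the call (32 of them with an estimated correlation), 27 gained it and 2 turned. Of the summary values, 180 combinations moved within their limit of 1.5 times or of the spread, 52 beyond it, and 1 lost its call. The cause was not tested except where a setting's own construction shows it (a stricter threshold, fewer arrays). Beyond changes given with the results, the block changed no call of a list or named gene.

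The number of genes changed in KLF4-labelled cells against control, 2544, and the number changed the same way in both groups, 2182, depended on the settings. They were 1052 and 926 with normexp, 974 and 839 with no filter on dim probes, 1497 and 1272 with only the 2 groups compared, 933 and 801 at an adjusted p of 0.01, 955 and 766 at 2-fold or more, 887 and 713 with spike-in scaling, 6744 and 5649 with the block, 7019 and 5788 with the block and median scaling, and 6023 and 5109 with the block and quantile normalization. Leaving out 1 array gave 881 to 1497 and 767 to 1270, fewer in every case. The share of higher calls among those for KLF4, 53.9%, was 67.0% with quantile normalization, 65.1% with the deposited value table, 74.9% with normexp, 84.7% with no filter, 74.1% with only the 2 groups compared, 85.7% at an adjusted p of 0.01, 89.1% at 2-fold or more, 74.1% to 87.5% leaving out 1 array, 89.4% with spike-in scaling, 43.9% with a floor on dim signals, 41.8% over genes above background on all 6 arrays and 32.4% with the block.

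Between IRF8-labelled cells and control, 3966 genes changed at least 2-fold and 4623 with spike-in scaling, against 8146. Between IRF8-labelled and KLF4-labelled cells, 4292 passed at an adjusted p of 0.01, 2576 at 2-fold or more and 2719 with spike-in scaling, against 6695. Spike-in scaling, fitted without the block, gave 0.67 for Irf8 between these groups. The 75th percentile less the spike-ins was lower on replicate 1 than 2 in every group, so calls lost with this scaling may reflect that offset. The covariance of the log2 fold changes against control, 1.02, was 1.042 with quantile normalization, 0.504 with normexp, 1.007 with the deposited value table, 0.774 with no filter, 0.527 over genes above background on all 6 arrays, 0.991 and 0.975 between different experiments, and 1.009 to 1.063 leaving out 1 array.

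Of the 18 gene lists, 0, 4 and 0 passed with an estimated correlation in the comparisons of IRF8-labelled cells with control, KLF4-labelled cells with control, and IRF8-labelled with KLF4-labelled cells (6, 6 and 4 at an unadjusted p under 0.05), and 18, 14 and 16 by fry, against 13, 13 and 10 by camera. Leaving out 1 array gave 13 in the first comparison, 10 to 13 in the second and 10 to 12 in the third. The lymphocyte list, with medians of -0.59 in IRF8-labelled and -0.40 in KLF4-labelled cells against control, was put down by camera without passing and up by fry (adjusted p = 4.73e-04 and 0.0102). Blnk, below background in control and KLF4-labelled cells, differed between them by -5.47e-04 with normexp, against a positive difference without it.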

Other observations

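The lists here and the tests of explanations were chosen after results had been seen. The block, the covariances between different experiments and the direct comparison were planned, and the prediction for the exchange of labels was written before the epidermal list was read. Genes of osteoclasts and lipid-laden macrophages rose in both transduced groups: of 27, 17 rose and 5 fell (18 and 3 with normexp, 16 and 3 with spike-ins) in IRF8-labelled cells against control (adjusted p = 1.45e-04, and adjusted p = 0.0876 with an estimated correlation) and 17 rose and 0 fell (18 and 3 with the block) in KLF4-labelled cells (adjusted p = 9.77e-13, and adjusted p = 0.0290 with an estimated correlation). Trem2, a lipid receptor of macrophages, rose 285-fold in IRF8-labelled and 316-fold in KLF4-labelled cells with 1 of the 2 control arrays above background, and Cd9, a tetraspanin, 16.1-fold and 240.2-fold (limma adjusted p = 2.57e-05 to 3.63e-04). Ribosome biogenesis genes fell: of 40, 0 rose and 38 fell in IRF8-labelled cells (adjusted p = 8.52e-09, and adjusted p = 0.0876 with an estimated correlation) and 0 rose and 7 fell (0 and 38 with the block, 0 and 3 with quantile normalization, 0 and 2 with normexp, 0 and 0 with spike-ins) in KLF4-labelled cells (adjusted p = 1.23e-05, and adjusted p = 0.133 with an estimated correlation). Dkc1, which modifies ribosomal RNA, fell 4.17-fold in IRF8-labelled cells, the RNA polymerase I subunit gene Polr1b 3.42-fold and the nucleolin gene Ncl 2.83-fold (adjusted p = 5.07e-05 to 0.00104). Of 18 genes associated with microglia, 13 rose and 3 fell in IRF8-labelled cells (adjusted p = 1.45e-04, and 0.0876 with an estimated correlation). In KLF4-labelled cells 7 rose and 1 fell (8 and 3 with the block), with adjusted p = 2.29e-04, and 0.0694 with an estimated correlation. There the median of 0.29 was 0.51 with bounds and -0.12 with normexp. Of 26 integrin and adhesion genes, 14 rose and 7 fell in IRF8-labelled cells (adjusted p = 0.0224, and adjusted p = 0.719 with an estimated correlation) and 12 rose and 1 fell (16 and 5 with the block) in KLF4-labelled cells (adjusted p = 3.01e-07, and adjusted p = 0.217 with an estimated correlation); Itgb7, the beta chain of a gut-homing integrin, rose at least 223-fold and at least 169-fold (adjusted p = 2.10e-05 and 7.21e-05). Many members of these lists also stand in the monocyte or lysosome lists.

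Cholesterol synthesis genes were lower in KLF4-labelled cells: of 23, 0 rose and 15 fell (0 and 6 with normexp, 0 and 0 with spike-ins) (adjusted p = 8.34e-05, and adjusted p = 0.0694 with an estimated correlation), with Cyp51 1.90-fold, Nsdhl 1.70-fold and Lss 1.67-fold lower (adjusted p = 0.00745 to 0.0306). In IRF8-labelled cells 2 rose and 7 fell (2 and 14 with the block, 0 and 7 with normexp, 0 and 2 with spike-ins) (adjusted p = 0.284). Of 36 oxidative phosphorylation genes 3 rose and 6 fell (8 and 9 with the block, 9 and 5 with quantile normalization, 1 and 6 with normexp, 0 and 0 with spike-ins) in IRF8-labelled cells (adjusted p = 0.867) and 0 rose and 0 fell (0 and 20 with the block) in KLF4-labelled cells, by limma (0 and 7 at an unadjusted p under 0.05), while camera passed downwards (median -0.23, adjusted p = 0.00598, and adjusted p = 0.217 with an estimated correlation). Glycolysis genes (21 tested) and epidermal and epithelial genes (41 tested) did not pass: of the former 3 rose and 5 fell (3 and 9 with the block) in IRF8-labelled cells and 2 rose and 2 fell (2 and 0 with normexp, 0 and 1 with spike-ins) in KLF4-labelled cells (adjusted p = 0.867 and 0.139), and of the latter 7 rose and 12 fell (4 and 10 with normexp) and 3 rose and 5 fell (7 and 11 with the block, 6 and 3 with quantile normalization, 0 and 2 with normexp, 3 and 0 with spike-ins) (adjusted p = 0.867 and 0.736). In the direct comparison, ribosome biogenesis genes were lower in IRF8-labelled than in KLF4-labelled cells, 1 higher and 33 lower (0 and 21 with spike-ins) (adjusted p = 4.59e-09, and adjusted p = 0.173 with an estimated correlation), and genes associated with microglia higher, 11 higher and 4 lower (adjusted p = 0.00733, and adjusted p = 0.173 with an estimated correlation). The others did not pass there: osteoclast 11 higher and 6 lower (5 and 5 with spike-ins), cholesterol 7 higher and 1 lower (11 and 1 with the block, 0 and 1 with spike-ins), integrin 8 higher and 9 lower (4 and 7 with spike-ins), glycolysis 2 higher and 5 lower (0 and 4 with spike-ins), oxidative phosphorylation 5 higher and 0 lower (16 and 4 with the block, 8 and 0 with quantile normalization, 3 and 0 with normexp, 0 and 0 with spike-ins) and epidermal 8 higher and 14 lower (13 and 16 with the block, 3 and 11 with normexp), with adjusted p = 0.433, 0.0861, 0.967, 0.734, 0.0861 and 0.818 in that order. With the block, cholesterol (0.0406) and oxidative phosphorylation (0.0288) passed in the direct comparison, and leaving out 1 array changed no call of these 8 lists.

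The Klf4 probe stayed at the control level on the arrays labelled KLF4 (log2 difference 0.00448). The explanation that these cells were hardly transduced is argued against by their fold changes, which correlated between the experiments at r = 0.901 across genes. A probe outside the transduced sequence remains a candidate explanation, since the difference of 0.00448 rests on a single probe whose position is not given. An exchange of the IRF8 and KLF4 labels could also leave Klf4 high where it was found. Of the epidermal genes that differed, 14 were higher on KLF4-labelled and 8 on IRF8-labelled arrays. That is short of the 3 times set beforehand as evidence against an exchange, so it cannot be told apart. Among other scalings, the block and normexp, only normexp reached that (11 and 3). Irf8 was higher on IRF8-labelled arrays, as labelled (adjusted p = 0.00210, and 0.213 with spike-in scaling and no block). Its probe is not shown to read the transduced sequence. That KLF4 did not raise its own transcript while IRF8 raised it is the biological reading the design gives, and it stays open.

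Of the genes raised in KLF4-labelled cells, 86.2% were also raised in IRF8-labelled cells. If cells of the IRF8 sample had been mixed into the KLF4 sample, genes raised at least 100-fold by IRF8 would stand at a single share of their IRF8 level. Of 117 such genes, 15 were not above background on either KLF4-labelled array while 10 stood at or above their IRF8 level, and the share ran from 0.329% at the 10th percentile through a median of 7.71% to 84.1% at the 90th, which argues against such mixing as the whole source. Shared control arrays as the whole source are argued against by fold changes from different experiments, which share no array and had covariances of 0.991 and 0.975 against 1.02 over all arrays, though part of the shared calls may come from them. A program common to both factors, the biological explanation the groups give, stays open and was not tested.

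More genes passed for KLF4 with the replicate block (6744) than without (2544), with 2188 higher and 4556 lower against 1372 and 1172. An offset between the experiments or slides is a candidate source of the larger count, since the block lowered the median standard error by 51.3%. Scaling may set the excess of falls: the share of higher calls with the block was 43.9% with quantile normalization and 33.2% with median scaling, between the limits set for a decision, so it cannot be told apart from a real excess of small falls. No biological explanation was tested.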
